A study of Mus musculus with 3 samples.

How the data were processed

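Single-nucleus RNA sequencing (10x Genomics 3' chemistry, in which a short sequence at the 3' end of each transcript is read and each molecule carries a unique molecular identifier, UMI) was done on frozen livers of male C57BL6 mice. There were 3 libraries. Each was made from 20 mg of liver per mouse, pooled over all mice of 1 diet and treatment group, so each group had 1 library and no animal could be told from another. The deposited values were raw UMI counts per gene and droplet barcode, not normalised, as whole numbers for every barcode including empty droplets. Reads were counted with Cell Ranger 8.0.1 per the file headers, on the mouse genome GRCm39 per the submitters' processing notes. The deposited files paired every gene identifier with a symbol, and gene names were taken from them. No genome coordinates are given, because the annotation at hand was of another build. Counts of near-identical gene copies, such as the Mup, Cyp2 and Gstm families, are uncertain, because a 3' read can fit more than 1 copy.

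Nuclei were called in each library separately. A UMI cutoff was set in the manner of Cell Ranger and came to 4622 UMIs in the CD (control diet) library, 3688 in the MD (MASH diet) library and 3848 in the MD+GPPD library. It was passed by 7588, 6034 and 6021 barcodes. Barcodes below it with at least 500 UMIs were added where their profile departed from the ambient profile, the summed counts of barcodes with at most 100 UMIs, in a Monte Carlo comparison with 10000 simulated profiles (Benjamini-Hochberg level 0.01). This added 2256, 3770 and 4492 barcodes. Called barcodes needed at least 300 genes and at most 5% mitochondrially encoded UMIs, a limit that removed 85, 32 and 14. Doublets were marked per library with scrublet at an expected rate of 0.8% per 1000 nuclei, and 904 (9.26%), 645 (6.60%) and 968 (9.22%) were removed. The remaining nuclei numbered 8855, 9125 and 9530.

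Nuclei of the 3 libraries were clustered together without integration, because library and group are the same thing. Counts were scaled to 10000 per nucleus and log-transformed. The clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1. Of 29 clusters, 27 took a name from 16 marker sets fixed before the data were examined, and named classes are called "-like". A cluster was left unnamed when its leading 10 genes held at least 2 markers of other classes, a limit set after the data were seen, or when its nuclei were shallow and led by none of its own markers. Clusters 11 and 17 stayed unnamed. They held 0.892% of the CD nuclei, 4.60% of the MD nuclei and 3.29% of the MD+GPPD nuclei. Cluster 11 was shallow, with a median of 1109.5 UMIs, scored highest as hepatocyte, was led by cell cycle genes such as Top2a and Diaph3 and held 22 CD, 204 MD and 248 MD+GPPD nuclei, and cluster 17 mixed Kupffer cell and endothelial markers. Cluster 25, named hepatocyte-like, had the T-cell marker Themis among its leading 10 genes against all clusters, but no marker of another class against the clusters of other classes. Themis reached 562 CPM in hepatocyte-like cluster 8 and 382 in cluster 22, and the T-cell genes Skap1, Cd3e and Bcl11b stood at 0.370, 0.222 and 0.185 in cluster 25. Cluster 28 was led by acute phase genes such as Saa1, Saa2, Mt2 and Lcn2, and cluster 1, with 20 nuclei, by interferon-induced genes such as Rsad2, Mx1 and Ifit3. Both were named hepatocyte-like.

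Comparisons were made in 4 classes: hepatocyte-, macrophage-, stellate- and sinusoidal endothelial-like nuclei. UMIs were summed per class and library and scaled to 1 common class total, giving CPM (counts per megacount). Each value has an exact Poisson 95% interval, each ratio an exact conditional 95% interval, and each share of nuclei an exact Clopper-Pearson 95% interval. These intervals cover counting error only. With 1 library per group there was no test between groups and no p-value. A gene with a count of 0 in a library was set to 3 UMIs there, and its fold is a lower bound.

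The genes named by size followed a rule fixed before the data were examined. In hepatocyte-like nuclei these were the 6 highest and 6 lowest ratios, and in each other class the 3 highest and 3 lowest. Candidates needed a proper symbol, at least 50 CPM in the higher library, at least 50 UMIs over both libraries and an interval of the ratio that left out 1. In the 3 other classes the level also had to be at least 2 times that of the hepatocyte-like nuclei of the same library. Map4k4 was named in every class. Of the genes the rule picks, 1 in hepatocyte-like nuclei is left out of the text. The text also names members of 32 gene lists fixed at the same time, 27 of them read in 1 class and 5 in all 4 classes. For each list the median log2 ratio was taken over members with at least 20 UMIs in the libraries compared, and members at least 1.5-fold higher or lower with an interval leaving out 1 were counted. The percentile of the median among 10000 random lists of equal size, matched on mean expression, describes these libraries and is not a test of the diets or the compound. Lists overlap: Mt2 and Mt1, for instance, serve the acute phase list here and a glucocorticoid panel in the closing section. Classes were named by marker genes, so cells that lost their identity could fall outside their class. The sinusoidal endothelial identity and stellate quiescence lists therefore cannot exclude such a loss.

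Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, used only for its TMM scaling factors on the deposited counts.

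The steps were tested on simulated data drawn from the real profiles, over the 8 comparisons of 4 classes, with 9353 to 16315 genes each. The interval held 1 for 95.0 to 96.1% of unchanged genes. It left out 1 on the right side for 61.2 to 95.5% of genes changed 1.5-fold, 85.1 to 98.5% of genes changed 2-fold and 98.5 to 100% of genes changed 4-fold. The intervals cover counting error only, so these rates do not show how they perform for differences between pools of animals. In macrophage-like sums of the CD library cleared of hepatocyte markers and mixed with 20% ambient RNA, 19.8% was recovered. The share is read from those same markers, so this checks the calculation and not how accurate the subtraction is on real nuclei.

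Shares of nuclei, list medians and the genes named by size, with Map4k4, were computed again with the UMI cutoff alone, with 1 fixed cutoff of 1000 UMIs, without the mitochondrial limit, with doublets kept and with Leiden resolution 0.5. Expression results were also computed with TMM scaling, with every nucleus weighted equally, with ambient RNA subtracted, with nuclei thinned to 1000 UMIs and, for lists, with no minimum of UMIs per member. Alternatives added after the data were seen were leaving out cluster 25, leaving out the MD and MD+GPPD nuclei in clusters made mostly of CD nuclei, counting cluster 17 as macrophage-like, another ambient profile, counting the clusters left unnamed with the UMI cutoff alone as hepatocyte-like, and all alternatives for the shares of dendritic-, T or NK-, B- and cholangiocyte-like nuclei. The positions between MD and CD, the shares of nuclei with a UMI of a gene (apart from thinning) and the lists in barcodes of at most 100 UMIs were computed once. Vascular endothelial-, dendritic-, T or NK-, B-, cholangiocyte- and mesothelial-like nuclei were left out of the expression comparisons, whose 4 classes were fixed before the data were examined.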

Results

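Liver nuclei were sequenced from 3 groups of male C57BL6 mice, with 1 library of pooled livers per group and no replicates, so no difference below has a replicate check. The CD group ate a control diet with 10 kcal% fat. The MD group ate a diet that induces metabolic dysfunction-associated steatohepatitis (MASH), a fatty liver disease with inflammation and scarring, with 20 kcal% fructose, 40 kcal% fat and 2% cholesterol. The MD+GPPD group ate the MASH diet and received glucosyl pyrrolo-pyrimidinone (GPPD), by the series title an inhibitor of the kinase MAP4K4, by intraperitoneal injection of 10 mg/kg, 3 times a week. Feeding started at 8 weeks of age and lasted 30 weeks, and the CD and MD groups were injected with vehicle containing 0.2% DMSO. The labels do not say which vehicle carried GPPD, so the vehicle could differ in every comparison of MD+GPPD with MD. The CD library held 130158278 UMIs, the MD library 90284870 and the MD+GPPD library 90829858. After calling, the libraries held 8855, 9125 and 9530 nuclei with median depths of 8947, 5451 and 4328 UMIs. Within a class the depths were closer: hepatocyte-like nuclei had medians of 11220, 11246.5 and 11190 UMIs, and macrophage-like nuclei 3449, 3129 and 3166.

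The diet comparison, MD against CD, shows what the MASH diet goes with in each cell class. Macrophage-like nuclei made up 3.29% (95% interval 2.92 to 3.68) of the CD library and 11.6% (10.9 to 12.2) of the MD library, a ratio of 3.51 (3.08 to 4.02). Hepatocyte-like nuclei of the MD library had higher levels of genes for fat synthesis and storage and of fetal and tumour-associated genes, and lower levels of genes for cholesterol synthesis. Macrophage-like nuclei of that library carried the genes of lipid-associated macrophages, which handle lipid and debris in fatty liver, and 11 of 22 resident Kupffer cell genes were lower there. In its stellate-like nuclei 19 of 38 matrix and myofibroblast genes were higher. Interferon response genes were mostly higher in hepatocyte-, stellate- and sinusoidal endothelial-like nuclei, and 11 of 34 were in macrophage-like nuclei.

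Other shares of nuclei also differed between these libraries. Hepatocyte-like nuclei made up 74.3% (73.3 to 75.2) of the CD library and 49.4% (48.4 to 50.5) of the MD library, a ratio of 0.666 (0.641 to 0.691). Stellate-like nuclei, from the cells that store vitamin A and make scar matrix, made up 8.39% and 13.0%, a ratio of 1.55 (1.42 to 1.70). Dendritic-like nuclei numbered 12 in the CD library and 223 in the MD library, a ratio of shares of 18.0 (10.1 to 35.4). The ratio was 4.97 (3.72 to 6.75) for T or NK-like nuclei, 4.65 (2.81 to 8.07) for B-like nuclei and 2.22 (1.72 to 2.90) for cholangiocyte-like nuclei, which line bile ducts. Sinusoidal endothelial-like nuclei had the smallest difference of the 4 classes compared, 9.80% against 11.2%, a ratio of 1.14 (1.04 to 1.25). Among named nuclei other than hepatocyte-like ones, the macrophage-like share was 13.2% in the CD library and 25.1% in the MD library. These shares depend on how nuclei are called and named: with the UMI cutoff alone the ratio was 7.75 for macrophage-like and 3.98 for cholangiocyte-like nuclei, and 0.801 (0.575 to 1.11) for B-like nuclei, in the other direction, where 1.37% of the CD nuclei were named B-like against 0.215% in the reported set. The B-like cluster under that cutoff had a median of 15071.5 UMIs, against 1415.5 for the B-like cluster of the reported set. The latter lies below the UMI cutoff of every library, so the B-like ratios are not of the same nuclei. The UMI cutoff alone left no dendritic-like cluster. The dendritic-like ratio was 9.66 with doublets kept, and the T or NK-like ratio 3.30 with 1 fixed cutoff of 1000 UMIs.

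**Figure D1:**
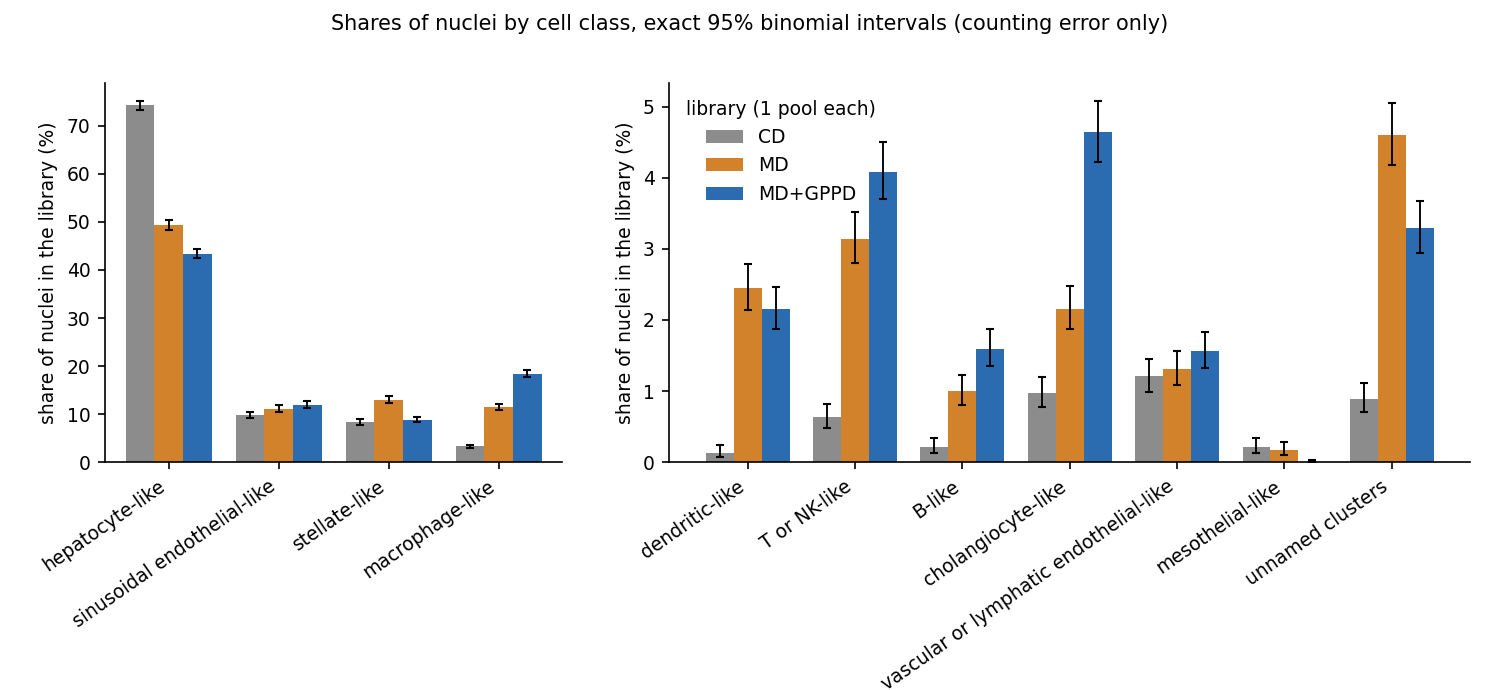
Share of nuclei (%, vertical axis from 0) by cell class in the CD, MD and MD+GPPD libraries, with exact 95% binomial intervals that cover counting error only. The macrophage-like share is 3.29, 11.6 and 18.4%, and the hepatocyte-like share 74.3, 49.4 and 43.4%.

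The genes of hepatocyte-like nuclei with the largest ratios of MD over CD were Ly6d, which encodes a cell surface protein, at 1160-fold (453 to 4260, on 4 UMIs in the CD library), and Ephb2, a receptor for ephrins, at 484-fold (270 to 970). Nrg1, a ligand of ErbB receptors, was 45.8-fold (41.3 to 50.9) higher, at 198 against 4.33 CPM. Mapt, which encodes tau, was 28.2-fold (25 to 31.9) higher and Ntrk2, a neurotrophin receptor, 26.0-fold (23.2 to 29.2). Hsd3b5, a steroid-metabolising enzyme typical of male liver, was 147 times lower (115 to 191), at 165 CPM in the CD library and 1.12 in the MD library. Serpina1e, of the antitrypsin family, was 37.0 times lower (34.5 to 39.8). Egfr, the epidermal growth factor receptor, was 20.2 times lower (19.9 to 20.4), at 7197 against 357 CPM. Mup7, a major urinary protein, was 17.0 times lower (15.5 to 18.6), Clec2h 16.5 times (14.6 to 18.7) and Keg1 14.0 times (13.4 to 14.7). CD nuclei of this class lay mostly in clusters 0, 2, 4 and 7, and MD nuclei in clusters 8, 21, 22, 25 and 28.

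Of 22 measured genes of de novo lipogenesis, which builds fatty acids from sugar, 14 were at least 1.5-fold higher in the MD library and 0 lower, with a median log2 ratio of 0.90 (percentile 100). Pnpla3, a lipid droplet protein, was 22.1-fold (20.1 to 24.3) higher, Scd1, which desaturates fatty acids, 7.37-fold (7.25 to 7.50) and Fasn, the fatty acid synthase, 3.83-fold (3.73 to 3.93). Of 24 genes of lipid droplets and fatty acid uptake, 16 were higher and 0 lower (median 1.19, percentile 100), with Cidea at 32.1-fold (22.7 to 46.7) and Plin4 at 5.26-fold (4.90 to 5.65). Cholesterol synthesis and SREBP2 target genes lay the other way: 13 of 26 were lower and 0 higher (median −0.56, percentile 0). Sqle, which epoxidises squalene, was 12.5 times lower (10.5 to 15.1) and Idi1 6.10 times (5.55 to 6.71). LXR target and sterol efflux genes were higher in 6 of 13 cases and lower in 0 (median 0.56, percentile 99.7), with the sterol exporter Abcg8 at 3.53-fold (3.47 to 3.60). The median of all genes in hepatocyte-like nuclei was 0.27 above 0 and moved to −0.01 with TMM scaling, a shift of −0.28. Relative to that shift the lipogenesis median was 0.62 and the cholesterol median −0.84.

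The medians of 3 further metabolic lists lay above 0 and turned below it with TMM scaling. PPAR alpha target and fatty acid oxidation genes had a median of 0.21, which turned to −0.08 with TMM scaling, with 9 of 34 higher and 1 lower (percentile 91.9). Among them Fgf21, a fasting and stress hormone, was 19.8-fold (17.3 to 22.8) higher and Cyp4a14 2.00 times lower (1.92 to 2.09). Lipoprotein secretion genes had a median of 0.22, −0.06 with TMM scaling, with 7 of 19 higher and 3 lower (percentile 97.1). Apoa4 was 25.1-fold (22.8 to 27.7) higher and Sort1 3.21 times lower (2.91 to 3.55). Genes of gluconeogenesis, glycolysis and fructose use had a median of 0.01, −0.27 with TMM scaling, with 3 of 23 higher and 2 lower (percentile 56.5). Pck1, of gluconeogenesis, was 2.21 times lower (2.18 to 2.24).

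Stress and injury lists differed in direction in the hepatocyte-like nuclei of the MD library. The fetal, NRF2 and cell death lists had medians above 0, while the acute phase and endoplasmic reticulum stress lists went both ways. Of 19 measured fetal, progenitor and tumour-associated liver genes, 18 were higher and 0 lower (median 1.77, percentile 100). Among them were Anxa2 at 92.9-fold (65.9 to 135) and Spp1, osteopontin, at 11-fold (9.27 to 13.2). Spp1 is also a leading gene of cholangiocyte-like cluster 12. In barcodes of at most 100 UMIs it stood at 22.8 CPM in CD and 507 in MD, so ambient RNA may add to its ratio. Of 28 NRF2 target and oxidative stress genes, 12 were higher and 0 lower (median 0.53, percentile 99.9), with Gsta1 at 60.7-fold (40.5 to 95.1) and Nqo1 at 5.31-fold (4.55 to 6.21). Of 22 genes of cell death, p53 and senescence, 13 were higher and 0 lower (median 0.81, percentile 100), with the cell cycle inhibitor Cdkn1a at 7.41-fold (5.95 to 9.29) and the necroptosis effector Mlkl at 6.42-fold (5.76 to 7.16). Acute phase and complement genes went both ways, with 13 of 32 higher and 6 lower. Their median of 0.17 turned to −0.11 with TMM scaling (percentile 73.2), with Saa2 at 62.0-fold (41.7 to 96.2) higher and C3 2.14 times lower (2.10 to 2.19). Endoplasmic reticulum stress genes split evenly, 3 of 23 higher and 3 lower (median −0.07, percentile 4.31), with Ddit3 at 1.83-fold (1.68 to 1.98) and Ern1 1.76 times lower (1.73 to 1.79).

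In macrophage-like nuclei the genes with the largest ratios belonged to the lipid-associated list. Gpnmb, a lysosomal glycoprotein, had 0 UMIs in the CD library and 783 CPM in the MD library, at least 265-fold higher against a floor of 3 UMIs (lower 95% limit 216). Mmp12, an elastase, was 634-fold (114 to 25071, on 1 UMI in the CD library) higher, and Atp6v0d2, a proton pump subunit with 0 UMIs in the CD library, at least 100-fold against that floor (lower limit 81.4). Of 23 lipid-associated genes, 20 were higher and 0 lower (median 3.03, percentile 100). The median was 2.11 with the UMI cutoff alone and 2.44 with nuclei thinned to 1000 UMIs. Resident Kupffer cell genes were lower in 11 of 22 cases and higher in 2 (median −0.56, percentile 0). Marco, a scavenger receptor, was 105 times lower (43.9 to 327), Cd163, the haptoglobin-haemoglobin receptor, 30.9 times (25.3 to 38.1) and Timd4, a receptor for dying cells, 17.0 times (14.3 to 20.2). Tenm2 was 35.8 times lower (17.3 to 85.8) and Cd55 35.5 times (22.4 to 59.4). Cytokine, chemokine and adhesion genes were higher in 7 of 22 cases and lower in 2 (median 0.29, percentile 90.05), with the chemokine gene Ccl4 at 5.87-fold (3.03 to 13.0), Tnf at 3.68-fold (1.80 to 8.74) and Nlrp3 1.76 times lower (1.38 to 2.24). CD nuclei of this class lay mostly in cluster 13 and MD nuclei in clusters 16 and 14.

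Shares of nuclei with a UMI gave the same order. With nuclei thinned to 1000 UMIs, Gpnmb was found in 0 of 267 macrophage-like nuclei of the CD library, which allows a share of up to 1.37%, and in 30.9% (28.1 to 33.8) of those of the MD library. Clec4f, a Kupffer cell lectin, was found in 84.6% and 46.0%, and Timd4 in 46.4% and 4.04%. In sinusoidal endothelial-like nuclei, which should lack these genes and had median depths of 2838 and 2316.5 UMIs, the shares for Gpnmb were 0 and 0.396% and for Clec4f 1.15 and 1.39%. Thinning left out 24 macrophage-like nuclei of the CD library and 38 of the MD library. Unthinned shares were 0 and 48.1% for Gpnmb, 94.2 and 57.7% for Clec4f and 76.6 and 7.69% for Timd4.

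In stellate-like nuclei, 19 of 38 extracellular matrix and myofibroblast genes were higher in the MD library and 1 was lower (median 0.59, percentile 100). Cluster 10, led by matrix genes such as Lama2 and Col6a3, held 163 of the 743 CD nuclei of this class and 423 of the 1189 MD nuclei, so the list includes a shift between subclusters. Col1a1 was 6.76-fold (5.27 to 8.80) higher, Col1a2 2.91-fold (2.59 to 3.28), and Timp1, an inhibitor of matrix proteases with 0 UMIs in the CD library, at least 14.3-fold against a floor of 3 UMIs (lower limit 11.2). Ccn2, a matricellular growth factor, was 2.59 times lower (2.09 to 3.22). The stellate quiescence and retinoid storage list had a median of 0.02, −0.04 with TMM scaling, with 4 of 16 higher and 1 lower (percentile 78.0). Lrat, which stores vitamin A as ester, was 2.18-fold (1.98 to 2.40) higher and Ntm 1.58 times lower (1.53 to 1.64). The largest ratios in this class were those of the interferon-induced chemokine Cxcl10 at 19.1-fold (9.08 to 48.2), Dclk1 at 17.4-fold (10.4 to 31.4) and the interferon-induced Ifi27l2a at 12.2-fold (7.26 to 22.1). The lowest were those of Col25a1, 6.93 times lower (4.53 to 11), Ptprt, a receptor phosphatase, 5.92 times (5.21 to 6.75) and Adgrl3, a latrophilin receptor, 5.33 times (3.84 to 7.54). For Adgrl3 the log2 ratio was −0.09 with the UMI cutoff alone.

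In sinusoidal endothelial-like nuclei, 9 of 18 genes of capillarization and endothelial activation, the loss of the open sinusoidal state, were higher and 0 lower (median 0.84, percentile 100). Selp, the adhesion receptor P-selectin, was 8.38-fold (4.89 to 15.4) higher and Fabp4, a fatty acid binding protein, 4.26-fold (3.32 to 5.54). The sinusoidal endothelial identity list had a median of −0.05 with 2 of 20 genes higher and 2 lower (percentile 44.1). Its median was 0.49 with the UMI cutoff alone. The class itself was named by marker genes, so a small median cannot exclude a loss of identity. Lyve1 was 2.88-fold (2.42 to 3.44) higher and Ehd3 1.84 times lower (1.72 to 1.97). The largest ratios were those of Cfap69 at 83.8-fold (22.9 to 698) and Pcdh9, a protocadherin, at 80.8-fold (22 to 673), both on 2 UMIs in the CD library, and Wdr17 at 11.4-fold (9.07 to 14.6). The lowest were those of Col4a3, a basement membrane collagen, 6.12 times lower (4.33 to 8.86), Ifitm10 4.78 times (3.54 to 6.56) and Gna14, a G protein subunit, 4.41 times (3.59 to 5.46).

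Interferon response genes were higher in the MD library in 23 of 34 cases in hepatocyte-like nuclei (1 lower, median 1.31), 23 of 34 in stellate-like nuclei (0 lower, median 0.81) and 20 of 31 in sinusoidal endothelial-like nuclei (0 lower, median 0.81), each at percentile 100. In macrophage-like nuclei 11 of 34 were higher and 3 lower (median 0.27, percentile 97.7). Ifi44 was higher by 6.20-fold (4.77 to 8.14), 7.12-fold (3.92 to 14.4), 4.78-fold (3.07 to 7.78) and 3.47-fold (2.69 to 4.52) in hepatocyte-, macrophage-, stellate- and sinusoidal endothelial-like nuclei. Cell cycle genes were also higher, in 23 of 28 cases in hepatocyte-like nuclei (1 lower, median 1.58, percentile 100), 17 of 26 in macrophage-like nuclei (0 lower, median 1.18, percentile 100), 10 of 16 in stellate-like nuclei (0 lower, median 2.12, percentile 100) and 5 of 22 in sinusoidal endothelial-like nuclei (0 lower, median 0.49, percentile 99.8). Top2a, a topoisomerase of dividing cells, was 15.7-fold (9.26 to 28.8) higher in hepatocyte-like nuclei. Cluster 11, which was shallow, unnamed and led by cell cycle genes, is not part of these values. Clusters 24 and 20, also led by cell cycle genes, are: cluster 24 held 5 CD, 51 MD and 60 MD+GPPD macrophage-like nuclei, and cluster 20 held 10, 33 and 48 sinusoidal endothelial-like nuclei. The stellate value rests on few UMIs and was 0.28 both with doublets kept and with 1 fixed cutoff of 1000 UMIs, and the hepatocyte value ranged from 0.63 with nuclei thinned to 1000 UMIs to 2.57 with that fixed cutoff. The sinusoidal endothelial value was 1.84 with Leiden resolution 0.5 and 1.48 with the UMI cutoff alone.

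Map4k4, the gene of the compound's target, stood at 19 CPM in hepatocyte-like nuclei of the CD library and 26.9 in the MD library, 1.41-fold (1.32 to 1.52) higher. The log2 ratio of Map4k4 in hepatocyte-like nuclei was 0.50 (0.40 to 0.60). TMM scaling shifts the genes of this class by −0.28, so the difference is smaller with that scaling. Map4k4 was 1.52-fold (1.17 to 2.02) higher in macrophage-like nuclei. Its ratio was 0.992 in stellate-like nuclei, and 1.09 (1.00 to 1.18) in sinusoidal endothelial-like nuclei, where the log2 ratio turned to −0.0234 with Leiden resolution 0.5 and to −0.0141 with ambient RNA subtracted. The MAP4K family and JNK pathway list in hepatocyte-like nuclei had a median of 0.01, −0.27 with TMM scaling, with 4 of 26 higher and 3 lower (percentile 4.05). Dusp8, a phosphatase of JNK, was 4.15-fold (2.63 to 6.71) higher and Fos 3.59 times lower (2.95 to 4.41). YAP and TEAD target genes were higher in 8 of 19 cases and lower in 0 (median 0.28, percentile 60.4), with Ajuba at 2.72-fold (2.24 to 3.31). That median is about the size of the shift that TMM scaling gives to all genes of this class, so it comes near 0 with that scaling.

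A list set up to follow RNA quality also differed between the libraries, but RNA quality itself was not measured. Ambient RNA of the CD library held 2.83% mitochondrially encoded UMIs, so the list also depends on the ambient share. The list of mitochondrially encoded and nuclear-retained RNA had medians of −1.11, −0.88, −0.68 and −0.58 in hepatocyte-, macrophage-, stellate- and sinusoidal endothelial-like nuclei of the MD library against CD, each at percentile 0, with 14, 13, 11 and 7 of 15 genes lower, and mt-Co1 3.10 times lower (3.06 to 3.13) in hepatocyte-like nuclei. Ambient RNA made up an estimated 20.0% of the UMIs of macrophage-like nuclei in the CD library and 7.74% in the MD library, or 9.48% and 4.89% with the added ambient profile. Some log2 ratios moved by over 1.5 times in fold: with Leiden resolution 0.5 Cd55 was −1.27 and Pcdh9 2.80, with the UMI cutoff alone Gna14 was −0.80, Cfap69 3.52, Gpnmb 6.61 and Mmp12 6.55, with doublets kept Tenm2 was −3.37, and with thinning Ly6d was 8.49. The fetal list was 2.58 with the added ambient profile subtracted, and the interferon list in stellate-like nuclei 1.55 with the UMI cutoff alone.

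**Figure D2:**
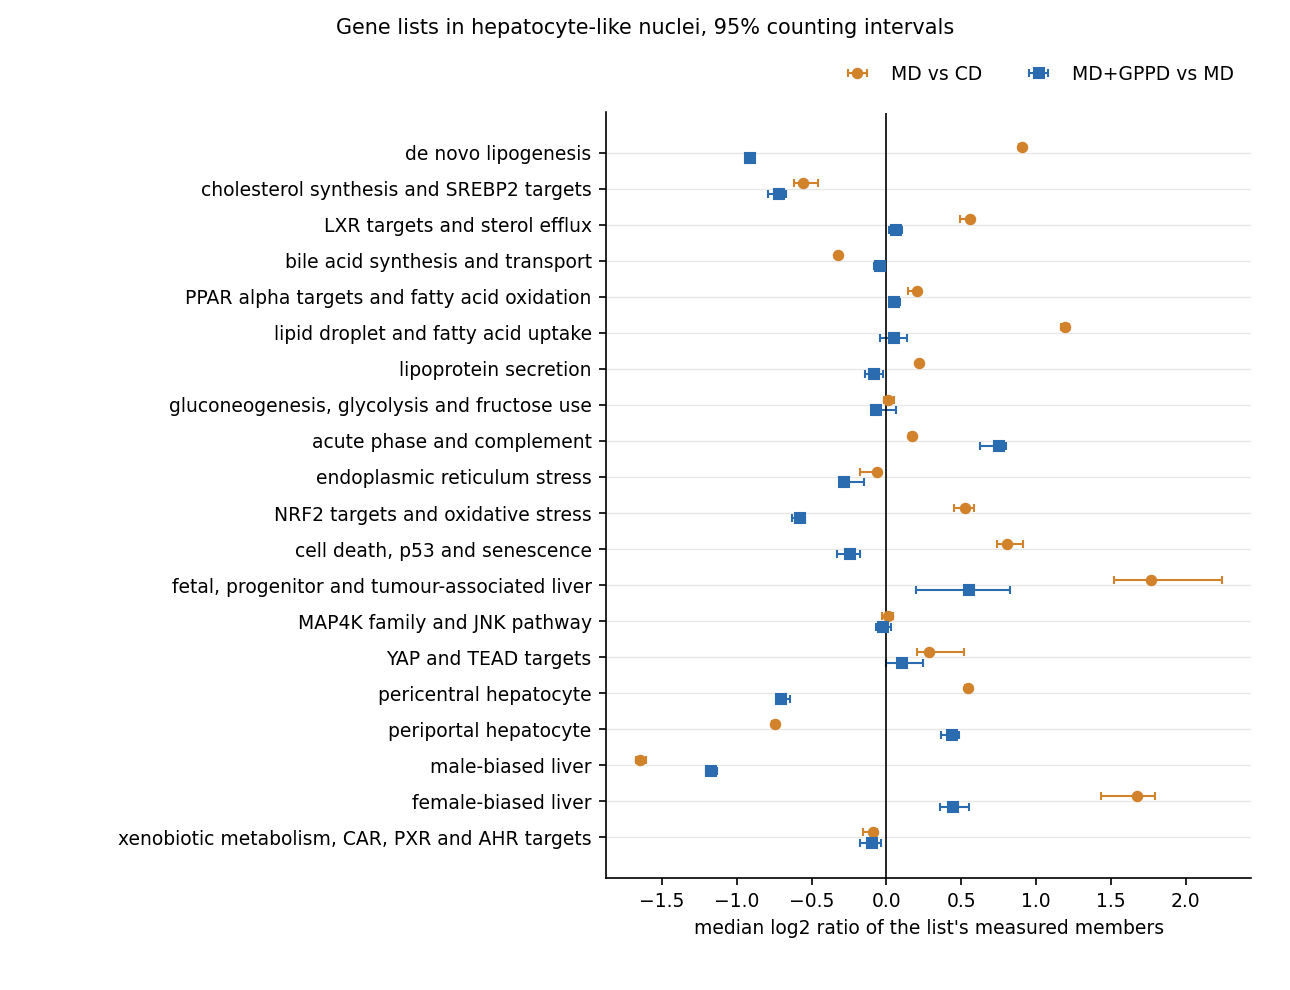
Median log2 ratio (horizontal axis) of each gene list read only in hepatocyte-like nuclei, for MD against CD and for MD+GPPD against MD, with bars for the 95% counting interval of the median. De novo lipogenesis lies at 0.90 and −0.91, while cholesterol synthesis lies below 0 in both comparisons, at −0.56 and −0.72.

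The compound comparison, MD+GPPD against MD, shows what the MAP4K4 inhibitor goes with under the MASH diet. In hepatocyte-like nuclei, genes of fat synthesis were lower in the MD+GPPD library, and Mt1, Mt2, Zbtb16 and Fkbp5, genes that respond to glucocorticoid hormones, were higher. Macrophage-like nuclei made up 18.4% (17.7 to 19.2) of the MD+GPPD library and 11.6% of the MD library, a ratio of 1.60 (1.48 to 1.72). The ratio was 1.32 with Leiden resolution 0.5 and 1.37 with cluster 17 counted as macrophage-like. Of the interferon response genes, 13 to 16 were lower in each of the 4 classes and 0 higher. In stellate-like nuclei the matrix list differed little. The quiescence list had a median log2 ratio of −0.46, with 6 of 16 genes lower and 2 higher. Stellate-like nuclei made up 8.86% of the MD+GPPD library against 13.0%, a ratio of 0.680 (0.622 to 0.743).

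The other shares were 43.4% (42.4 to 44.4) against 49.4% for hepatocyte-like nuclei, a ratio of 0.878 (0.842 to 0.916), and 12.0% against 11.2% for sinusoidal endothelial-like nuclei, a ratio of 1.07 (0.986 to 1.17). Cholangiocyte-like nuclei made up 4.64% against 2.16%, a ratio of 2.15 (1.81 to 2.55), T or NK-like nuclei had a ratio of 1.30 (1.11 to 1.52), B-like nuclei 1.60 (1.23 to 2.10) and dendritic-like nuclei 0.88 (0.725 to 1.07). Mesothelial-like nuclei numbered 0 in the MD+GPPD library, which allows a share of up to 0.0387%, and 16 in the MD library. Of named nuclei other than hepatocyte-like ones, 34.6% were macrophage-like in the MD+GPPD library and 25.1% in the MD library, and 16.6% against 28.3% were stellate-like. With the UMI cutoff alone the hepatocyte-like ratio was 1.25 and the stellate-like ratio 1.04 (0.895 to 1.21), both in the other direction. That cutoff left 31.6% of the MD nuclei and 12.2% of the MD+GPPD nuclei unnamed, and with these counted as hepatocyte-like the ratio was 0.892 (0.854 to 0.931).

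Mt2 and Mt1, metallothioneins that bind zinc and copper, were 9.43-fold (8.63 to 10.3) and 6.97-fold (6.67 to 7.27) higher in hepatocyte-like nuclei of the MD+GPPD library. Zbtb16, a transcription factor, was 8.01-fold (7.82 to 8.20) higher, at 1105 against 138 CPM, with 443 in the CD library. Scara5, a ferritin receptor, was 7.95-fold (7.42 to 8.51) higher, the monooxygenase gene Fmo2 5.29-fold (4.86 to 5.77) and Fkbp5, a co-chaperone of the glucocorticoid receptor, 5.10-fold (4.94 to 5.27). The lowest ratios were those of Pnpla3, 18.6 times lower (16.7 to 20.7), Ppp1r3c, which directs a phosphatase to glycogen, 8.51 times (7.82 to 9.28), Fasn 8.14 times (7.78 to 8.52) and Acly, which makes acetyl-CoA for fat synthesis, 7.32 times (6.99 to 7.65). Angptl8, an inhibitor of triglyceride clearance, was 7.28 times lower (7.05 to 7.51) and Sult2a8, a bile acid sulfotransferase, 7.02 times (6.80 to 7.25). Fasn stood at 40.8 CPM in the MD+GPPD library, 332 in the MD library and 86.7 in the CD library. MD+GPPD nuclei of this class lay mostly in clusters 8, 21, 22, 25 and 28, as MD nuclei did, but in other proportions: cluster 25 held 1465 MD and 729 MD+GPPD nuclei, cluster 22 641 and 1560 and cluster 8 776 and 342, so these ratios include a shift between clusters.

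Of 22 lipogenesis genes, 14 were lower in the MD+GPPD library and 1 was higher (median −0.91, percentile 0). The exception was Lpin1, a phosphatidate phosphatase and transcriptional coregulator, at 4.51-fold (4.40 to 4.63). Cholesterol synthesis genes were lower still than in the MD library, in 16 of 26 cases with 0 higher (median −0.72, percentile 0), with Mvd 6.58 times lower (5.16 to 8.49) and Sc5d 3.25 times (3.16 to 3.33). Lipid droplet and fatty acid uptake genes split evenly, 5 of 24 higher and 5 lower. Their median of 0.05 turned to −0.06 with every nucleus weighted equally or without cluster 25 (percentile 96.6). Plin4 was 2.81-fold (2.70 to 2.92) higher and G0s2, an inhibitor of lipolysis, 2.52 times lower (2.48 to 2.57). LXR target genes had 1 of 13 higher and 1 lower (median 0.06, percentile 82.7), Scarb1 at 1.54-fold (1.5 to 1.58) and Pltp 3.24 times lower (2.97 to 3.55). PPAR alpha target genes had 6 of 34 higher and 3 lower (median 0.05, −0.0018 with the UMI cutoff alone). Cyp4a10 was 1.78-fold (1.71 to 1.86) higher and Pdk4 2.47 times lower (2.32 to 2.63).

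Lipoprotein secretion genes had 2 of 19 higher and 3 lower (median −0.09, percentile 24.6), with Angptl4, an inhibitor of lipoprotein lipase, at 3.05-fold (2.92 to 3.19). Genes of gluconeogenesis, glycolysis and fructose use had 6 of 23 higher and 7 lower (median −0.07, 0.01 with the UMI cutoff alone, percentile 30.0). Pck1 was 2.40-fold (2.37 to 2.44) higher, while G6pc, which releases glucose, was 3.06 times lower (2.99 to 3.13) and the pyruvate kinase gene Pklr 2.30 times (2.23 to 2.38). Acute phase and complement genes were higher in 17 of 32 cases and lower in 1 (median 0.75, percentile 100), with Il1r1 at 4.22-fold (4.14 to 4.31), Lcn2 at 3.76-fold (3.45 to 4.11) and the iron hormone gene Hamp 3.43 times lower (3.37 to 3.49). NRF2 target genes were lower in 14 of 28 cases and higher in 1 (median −0.58, percentile 0), with Gsta1 3.99 times lower (3.44 to 4.64). Endoplasmic reticulum stress genes had 2 of 22 higher and 1 lower (median −0.28, percentile 0.25), with Herpud1 at 2.40-fold (2.35 to 2.45) and Atf4 1.77 times lower (1.69 to 1.85). Genes of cell death, p53 and senescence had 4 of 22 higher and 4 lower (median −0.25, percentile 2.39), with Bcl2l1, an inhibitor of apoptosis, at 1.85-fold (1.79 to 1.91) and Gadd45a 1.99 times lower (1.79 to 2.22). Fetal and tumour-associated genes were higher again in 9 of 23 cases and lower in 1 (median 0.55, 0.13 with ambient RNA subtracted, percentile 100), with Cd44 at 3.57-fold (2.98 to 4.31) and Sox9 2.17 times lower (1.87 to 2.52).

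In macrophage-like nuclei Ccnd3, cyclin D3, was 5.75-fold (5.17 to 6.40) higher in the MD+GPPD library, Gas7 3.46-fold (2.86 to 4.21) and Shisa9 3.23-fold (2.62 to 4.02). Il1b, the cytokine interleukin-1 beta, was 3.56 times lower (2.86 to 4.45), at 20.2 against 72.0 CPM, with 114 in the CD library. Kif23, of cell division, was 2.90 times lower (2.35 to 3.59) and the interferon-induced Rsad2 2.51 times (2.09 to 3.01). Lipid-associated genes were higher in 4 of 23 cases and lower in 1 (median 0.23, percentile 100), with Cd63 at 1.74-fold (1.56 to 1.93) and Cd5l, a Kupffer cell protein, 2.01 times lower (1.95 to 2.06). Kupffer cell genes were lower in 10 of 21 cases and higher in 0 (median −0.61, percentile 0), among them Kcna2, 2.30 times (2.06 to 2.56), and Clec4f, 1.90 times. Gpnmb was found in 41.1% (38.7 to 43.5) of nuclei thinned to 1000 UMIs and Clec4f in 27.1%, after 84 shallower nuclei were left out. In sinusoidal endothelial-like nuclei the shares were 0.531% and 0.796%, at a median depth of 2648 UMIs. Unthinned shares in macrophage-like nuclei were 56.8% and 35.9%. In thinned nuclei Timd4 was found in 1.85%, against 4.04% in the MD library, while Cd163 was found in 2.81% (2.07 to 3.72) against 1.77% (1.05 to 2.79) and Mmp12 in 18.8% against 19.4%. Cytokine, chemokine and adhesion genes had 2 of 23 higher and 3 lower (median −0.21, percentile 1.53), with Vcam1 at 2.37-fold (2.22 to 2.53) and Ccl2 2.29 times lower (1.59 to 3.31). That median was 0.0031 with the UMI cutoff alone. MD+GPPD nuclei of this class lay mostly in cluster 14 and MD nuclei in cluster 16, and with Leiden resolution 0.5 the log2 ratio of Il1b was −0.95 and that of Gas7 0.93.

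In stellate-like nuclei Fmo2 was 9.12-fold (7.52 to 11.2) higher in the MD+GPPD library, Fam163b 7.93-fold (6.30 to 10.1) and the splicing factor gene Rbfox1 7.75-fold (5.68 to 10.8). Ptprt was 13.5 times lower (8.36 to 23.0), Hhip, an antagonist of hedgehog signals, 11.2 times (6.86 to 19.6) and Egfem1 8.14 times (6.59 to 10.1). Matrix and myofibroblast genes had 5 of 38 higher and 3 lower (median 0.15, percentile 99.6). Ccn2 was 4.13-fold (3.40 to 5.05) higher and Col6a3 1.89-fold (1.76 to 2.02), while Acta2, the smooth muscle actin of myofibroblasts, was 3.42 times lower (2.30 to 5.25). Col1a1 stood at 274 CPM against 191 in the MD library and 28.2 in the CD library. Quiescence genes were lower in 6 of 16 cases and higher in 2 (median −0.46, percentile 0), with Lrat 1.84 times lower (1.69 to 2.01) and Adamtsl2 at 3.68-fold (3.30 to 4.11). MD nuclei of this class lay mostly in cluster 9 (766, against 423 in cluster 10) and MD+GPPD nuclei mostly in cluster 10 (553, against 291 in cluster 9), and Col6a3 and Adamtsl2 are among the leading genes of cluster 10. These ratios therefore include the difference in subclusters.

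In sinusoidal endothelial-like nuclei Nav3 was 6.39-fold (4.55 to 9.20) higher, Sgcd, a sarcoglycan, 5.0-fold (3.72 to 6.84) and D5Ertd615e 4.29-fold (3.63 to 5.10). Slc15a2, a peptide transporter, was 67.1 times lower (25.8 to 249, on 4 UMIs in the MD+GPPD library), Ccbe1 11.9 times (6.96 to 21.8) and Rasgrf2 2.72 times (2.10 to 3.53). Identity genes had 1 of 20 higher and 2 lower (median −0.08, percentile 20.1, turning to 0.12 with Leiden resolution 0.5 and 0.22 with the UMI cutoff alone). Lyve1 was 1.59-fold (1.42 to 1.77) higher and Rspo3, which amplifies Wnt signals, 1.85 times lower (1.61 to 2.13). Capillarization and activation genes had 4 of 19 higher and 2 lower (median 0.21, percentile 99.1), with Cd34 at 2.78-fold (2.07 to 3.80) and the adhesion gene Icam1 1.81 times lower (1.47 to 2.23).

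Interferon response genes were lower in the MD+GPPD library in 16 of 33 cases in hepatocyte-like nuclei (median −0.56), 16 of 34 in macrophage-like nuclei (median −0.60), 14 of 34 in stellate-like nuclei (median −0.57) and 13 of 33 in sinusoidal endothelial-like nuclei (median −0.58), with 0 higher and percentile 0 in each. Isg15 was lower by 4.16 times (3.11 to 5.64), 3.32 times (2.01 to 5.60) and 3.99 times (2.31 to 7.33) in the first 3 of these classes, and the regulator Irf7 by 2.74 times (1.86 to 4.09) in the last. Cell cycle genes were lower in 7 of 28 cases in hepatocyte-like nuclei (median −0.09, percentile 36.9), 12 of 30 in macrophage-like nuclei (median −0.55, percentile 0) and 5 of 16 in stellate-like nuclei (median −0.50, percentile 0.06), with 0 higher in each. In sinusoidal endothelial-like nuclei 5 of 25 were higher and 0 lower (median 0.26, percentile 98.7). The cell cycle medians turned to 0.0697 in stellate-like nuclei thinned to 1000 UMIs, to −0.0188 with doublets kept and −0.56 with Leiden resolution 0.5 in sinusoidal endothelial-like nuclei, and to 0.03 with the UMI cutoff alone in hepatocyte-like nuclei. The hepatocyte value was −0.76 with doublets kept, −0.63 with no mitochondrial filter and −0.60 with 1 fixed cutoff of 1000 UMIs. Mcm2, of DNA replication, was 2.86 times lower (2.21 to 3.72) in hepatocyte-like nuclei.

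Map4k4 itself was 1.64 times lower (1.51 to 1.78) in hepatocyte-like nuclei of the MD+GPPD library, at 16.4 against 26.9 CPM. Its ratio was 1.01 in macrophage-like nuclei, where the log2 ratio turned to −0.49 with Leiden resolution 0.5, 1.1 (1.01 to 1.19) in stellate-like nuclei and 1.09 (1.01 to 1.17) in sinusoidal endothelial-like nuclei. The MAP4K family and JNK pathway list had 4 of 26 genes higher and 5 lower (median −0.02, 0.04 with TMM scaling, percentile 81.3). Jun was 2.00-fold (1.93 to 2.07) higher and Tnik, a kinase of the same family, 3.81 times lower (3.13 to 4.67). YAP and TEAD target genes had 4 of 20 higher and 3 lower (median 0.10, turning to −0.04 with the UMI cutoff alone or with thinning, percentile 93.5), with Tead1 at 1.98-fold (1.92 to 2.04) and Nuak2 2.32 times lower (2.13 to 2.53). The RNA quality list had medians of −0.44, −0.22, −0.24 and −0.35 in hepatocyte-, macrophage-, stellate- and sinusoidal endothelial-like nuclei (percentiles 0, 0.44, 0.61 and 0), but of its 15 genes only 2, 0, 0 and 1 were at least 1.5-fold lower, and 1 was higher in each class. These medians were −1.24, −1.20, −0.84 and −1.45 with ambient RNA subtracted. With the UMI cutoff alone the log2 ratio was −3.54 for Pnpla3, −2.13 for Acly and −0.74 for Rasgrf2, with Leiden resolution 0.5 it was 0.92 for Shisa9, and with thinning −0.61 for Rsad2.

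**Figure D3:**
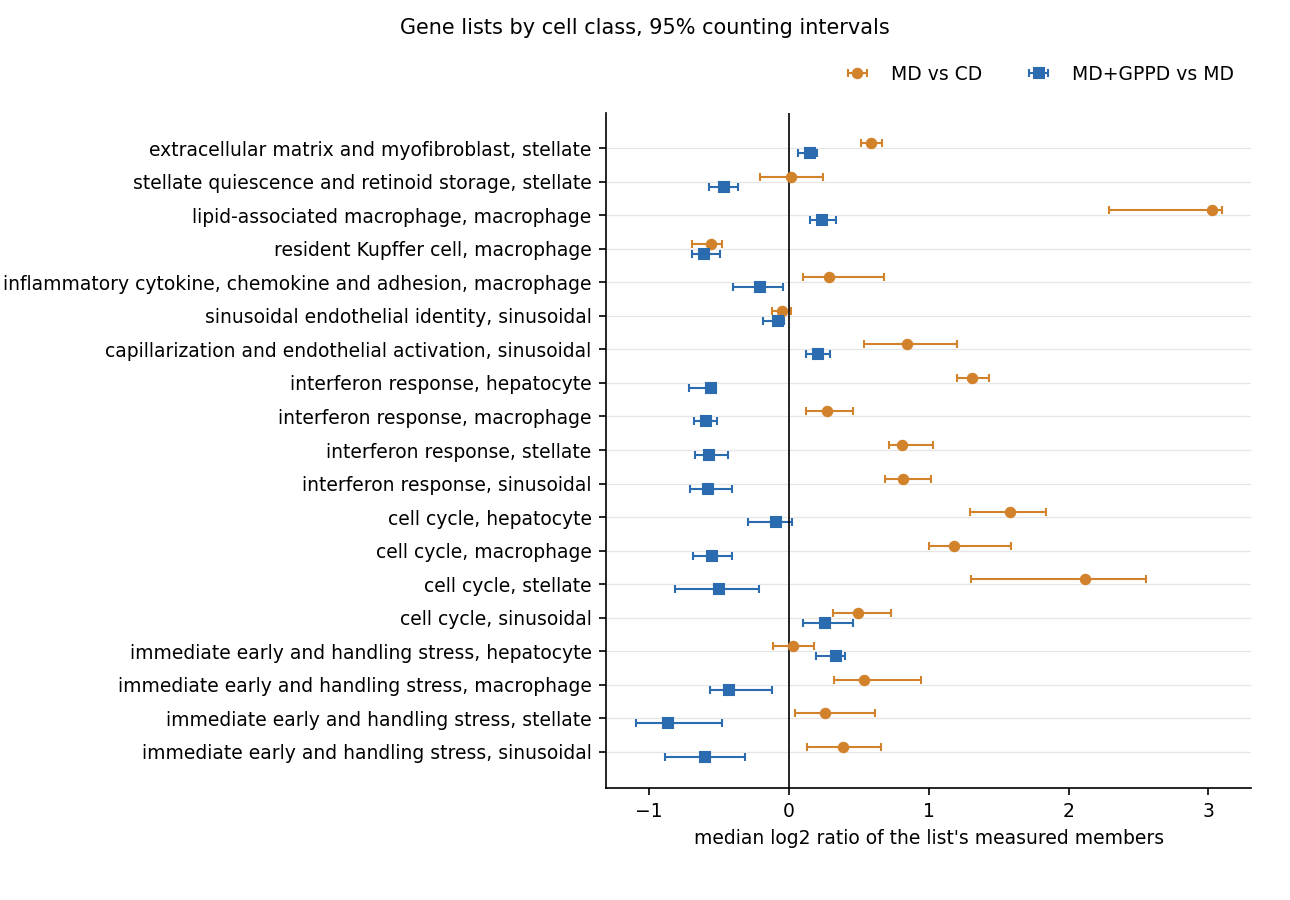
Median log2 ratio (horizontal axis) of gene lists for MD against CD and for MD+GPPD against MD, with bars for the 95% counting interval of the median. Shown are the lists read only in macrophage-, stellate- or sinusoidal endothelial-like nuclei. The interferon response, cell cycle and immediate early lists are shown in these classes and in hepatocyte-like nuclei. The lipid-associated macrophage list lies at 3.03 and 0.23, the extracellular matrix list at 0.59 and 0.15, and the interferon response lies above 0 for MD against CD and below 0 for MD+GPPD against MD in each of these classes.

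The last comparison set the MD+GPPD library between the MD and CD libraries. Of the 6 genes the naming rule picks as higher in hepatocyte-like nuclei of the MD library, 5 lay between MD and CD in the MD+GPPD library and 1, Ephb2, did not. Of the named genes lower there, 1, Egfr, lay between, at 983 CPM, and 5 did not: Hsd3b5 stood at 0.0383, Serpina1e at 5.44, Mup7 at 0.211, Clec2h at 3.85 and Keg1 at 30.2. In macrophage-like nuclei Mmp12 and Marco lay between and the other 4 named genes did not, Gpnmb among them at 1065 CPM. In stellate-like nuclei Cxcl10, at 12.7, and Ifi27l2a, at 47.0, lay between and Dclk1 and the 3 lower genes did not. In sinusoidal endothelial-like nuclei Pcdh9 lay between and the other 5 did not. For 6 of these genes the counting interval of the log2 ratio of MD+GPPD over MD held 0, so their position is open: Keg1 (−0.17 to 0.03), Marco (−1.64 to 2.01), Tenm2 (−3.39 to 0.36), Cd55 (−1.28 to 0.54), Pcdh9 (−0.40 to 0.22) and Ifitm10 (−0.87 to 0.28).

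Across all genes that differed between MD and CD by size, the position was tested with the MD nuclei split at random into a pair of parts, so that counting error was not shared. In hepatocyte-like nuclei, 62.4% of 242 genes higher in MD lay toward CD in the MD+GPPD library, against 51.2% in simulated unchanged nuclei, and 27.3% were past 1.5-fold toward CD and 9.92% past 1.5-fold away. Of 159 genes lower in MD, 41.5% lay toward CD, against 45.3% in the simulation, and 19.5% were past 1.5-fold toward CD and 29.6% away. In macrophage-like nuclei 34.3% of 362 higher genes and 35% of 286 lower genes lay toward CD, against 52.5 and 50.3%. In stellate-like nuclei the shares were 39.0% of 146 and 39.6% of 106, against 45.9 and 45.3%, and in sinusoidal endothelial-like nuclei 30.8% of 120 and 49.1% of 110, against 45.8 and 50%. In these 3 classes more genes were past 1.5-fold away from CD than toward it: 23.5 against 4.42% and 21.7 against 6.29% in macrophage-like, 25.3 against 13.0% and 30.2 against 14.2% in stellate-like, and 33.3 against 13.3% and 28.2 against 20% in sinusoidal endothelial-like nuclei, for genes higher and lower in MD. The split does not remove what is particular to the MD pool of animals.

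The genes named by size, and Map4k4, carry these identifiers in the files: Ly6d ENSMUSG00000034634, Ephb2 ENSMUSG00000028664, Nrg1 ENSMUSG00000062991, Mapt ENSMUSG00000018411, Ntrk2 ENSMUSG00000055254, Hsd3b5 ENSMUSG00000038092, Serpina1e ENSMUSG00000072849, Egfr ENSMUSG00000020122, Mup7 ENSMUSG00000073842, Clec2h ENSMUSG00000030364, Keg1 ENSMUSG00000024694, Gpnmb ENSMUSG00000029816, Mmp12 ENSMUSG00000049723, Atp6v0d2 ENSMUSG00000028238, Marco ENSMUSG00000026390, Tenm2 ENSMUSG00000049336, Cd55 ENSMUSG00000026399, Cxcl10 ENSMUSG00000034855, Dclk1 ENSMUSG00000027797, Ifi27l2a ENSMUSG00000079017, Col25a1 ENSMUSG00000058897, Ptprt ENSMUSG00000053141, Adgrl3 ENSMUSG00000037605, Cfap69 ENSMUSG00000040473, Pcdh9 ENSMUSG00000055421, Wdr17 ENSMUSG00000039375, Col4a3 ENSMUSG00000079465, Ifitm10 ENSMUSG00000045777, Gna14 ENSMUSG00000024697, Mt2 ENSMUSG00000031762, Zbtb16 ENSMUSG00000066687, Scara5 ENSMUSG00000022032, Mt1 ENSMUSG00000031765, Fmo2 ENSMUSG00000040170, Fkbp5 ENSMUSG00000024222, Pnpla3 ENSMUSG00000041653, Ppp1r3c ENSMUSG00000067279, Fasn ENSMUSG00000025153, Acly ENSMUSG00000020917, Angptl8 ENSMUSG00000047822, Sult2a8 ENSMUSG00000030378, Ccnd3 ENSMUSG00000034165, Gas7 ENSMUSG00000033066, Shisa9 ENSMUSG00000022494, Il1b ENSMUSG00000027398, Kif23 ENSMUSG00000032254, Rsad2 ENSMUSG00000020641, Fam163b ENSMUSG00000009216, Rbfox1 ENSMUSG00000008658, Hhip ENSMUSG00000064325, Egfem1 ENSMUSG00000063600, Nav3 ENSMUSG00000020181, Sgcd ENSMUSG00000020354, D5Ertd615e ENSMUSG00000029092, Slc15a2 ENSMUSG00000022899, Ccbe1 ENSMUSG00000046318, Rasgrf2 ENSMUSG00000021708 and Map4k4 ENSMUSG00000026074.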

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

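Barcodes with at most 100 UMIs hold RNA from outside the called nuclei. The report otherwise uses them only as the ambient profile, for calling nuclei and for subtracting ambient RNA. Several gene lists stood higher in these barcodes in the libraries of the MASH diet than in the CD library. These barcodes held 3076486, 4265108 and 3824564 UMIs in the CD, MD and MD+GPPD libraries. In the MD library the median log2 ratio over CD was 3.42 for lipid-associated macrophage genes, 2.83 for cytokine, chemokine and adhesion genes, 2.64 for fetal and tumour-associated genes, 2.27 for extracellular matrix and myofibroblast genes and 2.11 for capillarization and activation genes. In the MD+GPPD library it was 3.60 for the lipid-associated list, 2.82 for the cytokine list, 2.89 for the fetal list and 2.51 for female-biased genes. Lists of other non-hepatocyte classes stood higher in the MD library too, Kupffer cell genes at 1.54, sinusoidal endothelial identity at 1.31 and stellate quiescence at 1.21, and male-biased genes stood lower in the MD+GPPD library, at −2.81 with 23 of 24 lower. All 23 lipid-associated genes were at least 1.5-fold higher in both libraries. Gpnmb stood at 0.325, 95 and 122 CPM in the CD, MD and MD+GPPD libraries, Trem2 at 0.325, 59.8 and 81.8, Mmp12 at 0, 93.1 and 107 and Spp1 at 22.8, 507 and 598. Macrophage-like nuclei carried the same difference in Gpnmb and Mmp12 and were more numerous in these libraries. The minimum of 4-fold (log2 2) was set after the values were seen: at 2-fold, 22 of 64 values of the 32 lists pass, and at 4-fold 9 do. No test told apart RNA that leaked from such nuclei and RNA from cells lost before the libraries were made.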

How the results depend on the processing

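The alternatives were chosen before the data were examined, apart from these, chosen after seeing the data: leaving out cluster 25, leaving out the MD and MD+GPPD nuclei in CD clusters, counting the mixed cluster as macrophage-like, another ambient profile, counting the clusters that the UMI cutoff alone leaves unnamed as hepatocyte-like, and every alternative for the shares of dendritic-, T or NK-, B- and cholangiocyte-like nuclei. Counts below are of values under an alternative: for the shares of the 4 compared classes, 32 stayed within the interval of the reported value, 10 moved beyond it and 2 reversed. For the shares of those other classes, 32 stayed, 5 moved and 1 reversed. With the UMI cutoff alone there was no dendritic-like cluster and so no ratio. For the matrix, lipid-associated, lipogenesis and cholesterol lists, 68 stayed, 28 moved and 0 reversed. For the other lists 774 stayed, 257 moved and 7 reversed, and for the named genes and Map4k4 573 stayed, 157 moved and 2 reversed. Unless stated, the cause was not tested. No paired analysis was possible because each group has 1 library.

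With the UMI cutoff alone, the hepatocyte-like share ratio was 0.498 for MD against CD and 1.25 for MD+GPPD against MD, the latter reversed. That cutoff left 1810 MD and 696 MD+GPPD nuclei unnamed, of which 96.9% and 97.0% were hepatocyte-like in the reported set. Counted as hepatocyte-like, they gave ratios of 0.851 and 0.892, so the reversal comes from naming, while the cause of the move in MD against CD was not tested. The B-like ratio for MD against CD was 0.801 under that cutoff, reversed. Under that cutoff the macrophage-like ratio was 7.75 for MD against CD, the stellate-like ratio 2.10 for MD against CD and 1.04 for MD+GPPD against MD (reversed), and the sinusoidal endothelial-like ratio 1.32 for MD+GPPD against MD. Medians for MD against CD and MD+GPPD against MD were 1.12 and 0.27 for the matrix list, 0.66 and −0.80 for lipogenesis and −0.68 and −0.61 for cholesterol synthesis, and 2.11 for the lipid-associated list in MD against CD. For MD+GPPD against MD, the cytokine list in macrophage-like nuclei (0.0031), PPAR alpha targets (−0.0018) and immediate early genes in stellate-like nuclei (0.0128) reversed.

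With 1 fixed cutoff of 1000 UMIs, the share ratios for MD against CD were 0.699 (hepatocyte-like) and 4.08 (macrophage-like). With doublets kept, the hepatocyte-like ratio for MD+GPPD against MD was 0.814, the matrix medians 0.69 and 0.22 and the lipogenesis medians 0.93 and −0.88 in the 2 comparisons. There, immediate early genes in macrophage-like nuclei (−0.16, MD against CD) and cell cycle genes in sinusoidal endothelial-like nuclei (−0.0188, MD+GPPD against MD) reversed. With Leiden resolution 0.5, the macrophage-like ratio for MD+GPPD against MD was 1.32 and the lipid-associated median 0.38. There, cell cycle genes in sinusoidal endothelial-like nuclei (−0.56, MD+GPPD against MD) and Map4k4 in that class (−0.0234, MD against CD) reversed.

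With TMM scaling, lipogenesis was 0.62 and −0.85 and cholesterol synthesis −0.84 and −0.66. With equal weight per nucleus, lipogenesis was 0.71 and −0.97. With ambient RNA subtracted, the matrix list was 0.42 in MD against CD and lipogenesis −1.02 in MD+GPPD against MD, and 0.50 and −1.03 with the other profile. Map4k4 in sinusoidal endothelial-like nuclei reversed with the subtraction (−0.0141, MD against CD). With nuclei thinned to 1000 UMIs, the matrix list was 0.49 in MD against CD, lipogenesis 0.59 and −0.95, and cholesterol synthesis −0.84 in MD+GPPD against MD. Cell cycle genes in stellate-like nuclei reversed with thinning (0.0697, MD+GPPD against MD). The added alternatives gave a lipogenesis median of 0.94 without cluster 25 and 0.93 without the nuclei in CD clusters (MD against CD), and a macrophage-like ratio of 1.37 with the mixed cluster (MD+GPPD against MD). The classes compared with hepatocyte-like nuclei held fewer UMIs per nucleus. The UMI cutoffs above, which select nuclei by depth, moved some of their shares, but depth was not tested apart from calling and naming.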

Other observations

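In hepatocyte-like nuclei sex-biased genes differed between libraries. Of 25 male-biased genes, 21 were at least 1.5-fold lower in the MD library than in the CD library and 1 higher (median log2 ratio −1.65, percentile 0), and of 24, 17 were lower in the MD+GPPD library than in the MD library and 2 higher (median −1.17, percentile 0). Mup20 was an exception in both, at 2.34-fold (2.31 to 2.36) and 1.55-fold (1.54 to 1.56) higher, while Mup11 was 13.5 times lower (10.8 to 17.1) in MD+GPPD than in MD. Of 17 female-biased genes, 11 were higher in MD and 3 lower (median 1.67, percentile 100), with Sult1e1 at 161-fold (89.9 to 324) and Prlr 2.91 times lower (2.84 to 2.99). In MD+GPPD against MD, 7 were higher and 2 lower (median 0.44, percentile 99.9), with Cyp17a1 at 3.44-fold (3.08 to 3.84). All animals were male. Mup and Cyp genes share sequence, so their values are uncertain.

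Lobular zones differed in opposite directions in the comparisons. Pericentral genes were higher in MD than in CD in 13 of 26 cases and lower in 4 (median 0.54, percentile 100), with Slc1a4 at 12.0-fold (9.72 to 14.9). Periportal genes were lower in 15 of 26 and higher in 2 (median −0.74, percentile 0), with Igf1 3.73 times lower (3.67 to 3.80). In MD+GPPD against MD, pericentral genes were lower in 15 of 26 and higher in 1 (median −0.70, percentile 0), with Cyp2c29 4.48 times lower (4.32 to 4.64), and periportal genes higher in 9 of 26 and lower in 2 (median 0.44, percentile 100), with Igf1 at 2.62-fold (2.57 to 2.68) and Ass1 at 2.30-fold (2.26 to 2.34). Cluster 8, led by pericentral genes such as Glul and Lgr5, held 12 CD, 776 MD and 342 MD+GPPD nuclei of the 6575, 4510 and 4137 in this class, and cluster 7, led by Slc1a2, held 667, 38 and 2. The zone medians may therefore include how many nuclei of each zone were sampled. Because zone genes also shape the clusters, these counts cannot tell that from a change of the genes within nuclei. Xenobiotic metabolism genes went both ways, 5 of 26 higher and 7 lower (median −0.09, percentile 2.29) and 8 higher and 9 lower (median −0.09, percentile 28.2). Bile acid synthesis and transport genes had 5 of 26 higher and 7 lower in MD (median −0.33, percentile 0.18), with Cyp7b1 13.1 times lower (12.9 to 13.3). In MD+GPPD against MD, 5 were higher and 4 lower (median −0.04, 0.02 with TMM scaling, percentile 37.3), with Cyp8b1 3.84 times lower (3.56 to 4.14).

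Immediate early genes, which respond to handling within minutes, had medians for MD against CD of 0.03 in hepatocyte-like nuclei (−0.25 with TMM scaling, −0.03 with equal weight per nucleus, percentile 4.25), 0.53 in macrophage-like (percentile 98.8), 0.26 in stellate-like (−0.55 with the UMI cutoff alone, percentile 79.6) and 0.39 in sinusoidal endothelial-like nuclei (percentile 97.4). For MD+GPPD against MD they were 0.33, −0.43, −0.87 and −0.60 (percentiles 100, 0.01, 0 and 0), with Egr1 at 2.79-fold (2.53 to 3.07) higher in hepatocyte-like nuclei and 4.78 times lower (3.31 to 7.10) in stellate-like nuclei. The stellate median of −0.87 turned to just above 0 with the UMI cutoff alone. With ambient RNA subtracted, the immediate early medians for MD against CD were 1.94 in macrophage-like, 3.27 in stellate-like and 1.77 in sinusoidal endothelial-like nuclei, and the macrophage value was −0.16 with doublets kept. Circadian clock genes had medians for MD against CD of 0.32, 0.43, −0.01 and 0.07 in the same order (percentiles 94.5, 75.9, 31.8 and 61.2), the macrophage value turning to −0.18 with doublets kept and the sinusoidal endothelial value being 1.73 with ambient RNA subtracted. For MD+GPPD against MD they were 0.00, 0.01, 0.09 and −0.08 (percentiles 88.1, 64.1, 87.5 and 23.0), turning to −0.01 in macrophage-like and −0.07 in stellate-like nuclei with equal weight per nucleus. Arntl was 3.17 times lower (2.88 to 3.50) and Per1 2.82-fold (2.62 to 3.03) higher in hepatocyte-like nuclei of MD+GPPD against MD.

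The tests on fewer hepatocyte-like nuclei, time of day and a fasted state below were chosen only after the results were seen. Some MD hepatocyte-like nuclei, 175 or 3.88%, lay in clusters made mostly of CD nuclei, against 18 or 0.435% for MD+GPPD. Barcodes shared between libraries are excluded as the cause, since 0% of these nuclei shared one (upper limit 2.09%). CD nuclei mixed into the MD library are excluded as the whole cause: on a scale from CD at 0 to the other MD nuclei at 1 their position was 0.659 (0.628 to 0.673, over 671 genes), where mixing needs 0.25 or less. An animal on the MASH diet with a smaller response met its prediction of a lowered cholesterol synthesis median against CD, at −1.21 (−1.42 to −0.95). The other MD nuclei, at −0.53, met it too, so the test cannot tell a smaller response from an ordinary one. The value lies below −0.53, so it shows exposure to the diet rather than a smaller response in that list. With 1 pool, an animal and a subset of nuclei of many animals remain open.

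The larger macrophage-like share in MD+GPPD than in MD was set against 3 technical explanations. It kept a ratio of 1.54 (1.42 to 1.66) with 1 fixed cutoff for calling, 1.496 (1.39 to 1.61) with doublets kept and 1.49 (1.33 to 1.66) when taken relative to sinusoidal endothelial-like nuclei, so calling, doublet removal and fewer hepatocyte-like nuclei are each excluded as the whole cause. Recovery of macrophage nuclei that differs between pools, and an effect of the compound, were not tested, because each group is 1 pool.

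Lower lipogenic and higher glucocorticoid-responsive genes in MD+GPPD hepatocyte-like nuclei might come from the time of day, a fasted state or glucocorticoid signalling. For part of the glucocorticoid panel the MD library was the low one. Tsc22d3 stood at 158, 52.2 and 143 CPM in CD, MD and MD+GPPD, and Klf9 at 235, 138 and 218. The other panel genes stood higher in MD+GPPD than in CD, such as Fkbp5 at 406 against 58.8. Time of day cannot be told apart, since the difference between the arms of the clock was 0.93 at most (0.92 in hepatocyte-like, 0.93 in stellate-like, 0.37 in sinusoidal endothelial-like and −0.23 in macrophage-like nuclei). A fasted state cannot be told apart either, because the bound that would exclude it was reset after the value was seen. The PPAR alpha target median was 0.0487 (0.02 to 0.09) over 34 genes that go both ways, under the 0.58 set for a fasted state. The reset bound uses the SD over those genes (0.53), which is a spread between genes and not the error of the median. Glucocorticoid signalling across the whole liver cannot be told apart as well. Its lowest panel median was 0.52 in sinusoidal endothelial-like nuclei, under the 0.58 set beforehand, with 1.57 in macrophage-like and 1.25 in stellate-like nuclei. With ambient RNA subtracted, 5 of its 9 genes were higher and 3 lower in macrophage-like nuclei. The counts were 4 and 2 in sinusoidal endothelial-like nuclei and 7 and 0 in stellate-like nuclei. Mt1 and Mt2 are among the lower genes in macrophage- and sinusoidal endothelial-like nuclei. Before the subtraction they were 1.60- and 3.17-fold higher in macrophage-like and 1.94- and 2.06-fold higher in sinusoidal endothelial-like nuclei. With it, Mt1 fell to 0.0321-fold in macrophage-like and 0.0604-fold in sinusoidal endothelial-like nuclei. A count that the subtraction brings to 0 is set to 3 UMIs, so the lower values of Mt1 and Mt2 may reflect that floor. The sinusoidal endothelial median of 0.52 counts these genes as lower. The next log2 ratio above it, 0.61 for Klf9, passes 0.58. The miss therefore depends on Mt1 and Mt2 and does not speak against glucocorticoid signalling. Without the subtraction the medians were 1.53, 1.39 and 0.96 in macrophage-, stellate- and sinusoidal endothelial-like nuclei, with 7, 8 and 7 genes higher and 0 lower. Fkbp5 was then 9.71-, 3.30- and 2.28-fold higher, Zbtb16 10.2-, 18- and 15.9-fold and Per1 3.79-, 2.45- and 3.88-fold, and these 3 genes stayed higher in each class with the subtraction. All groups were injected 3 times a week, so injection as such is shared, and an effect of the compound remains open.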
